A study of Mus musculus with 8 samples.

How the data were processed

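Gene expression was measured on 8 one-colour Affymetrix whole-transcript arrays, each hybridised with biotin-labelled material made from total RNA of mouse T cells. Per the labels' protocols, T cells were isolated from the spleens of 4 wild-type C57BL/6 mice with a kit for untouched T cells of both the CD4 and the CD8 lineage. The cells were stimulated with beads carrying antibodies to CD3 and CD28 and kept for 48 h with either phosphate-buffered saline (PBS, the vehicle) or human beta-defensin-2 (hBD-2). The labels give the amount of hBD-2 as 60 µL/mL, a volume per volume, so the mass concentration is unknown. Each group holds 4 arrays numbered 1 to 4. The labels name 4 mice for the 8 arrays and do not say which array came from which mouse. If both arrays of a number share a mouse, the groups are not independent, and the tests without a block do not use that.

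The authors deposited 1 table of log2 expression values with 22203 probe sets and 8 array columns, and all 8 columns were used. Per the submitters' processing notes, the tools oligo and RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes into log2 values) were used. Their versions and settings and the annotation build are not given in the sources used here. The array medians of the deposited log2 values lay between 5.30 and 5.42, and single values between 1.73 and 12.8. RMA brings low signals towards a common floor, so a fold change of a dim gene is understated. No scanner intensities or detection calls were used here. The number of arrays limits the precision.

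A table of the platform's gene annotation gave exactly 1 gene symbol for 19572 probe sets and listed none with several. The other 2631 probe sets are not listed in that table and stay unnamed here. All 19572 symbols were looked up by gene identifier in a gene table of the assembly GRCm38.p6, and none changed. No coordinates are given, because the build behind the arrays is not given in the sources used here. For the 55 genes with several probe sets, the one with the highest mean over the 8 arrays was kept, which left 19505 genes. No gene was left out for being dim.

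The comparison of hBD-2 with PBS was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a block, a variance trend or robust estimation) on the deposited values. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05, and a further count took a fold change of at least 1.5. Fold changes are differences of log2 means, hBD-2 minus PBS, with their standard errors (SE). Adjusted p-values of genes are from this limma fit. A count "adjusted over the list alone" repeats the adjustment over the members of 1 gene list. Single values per array, such as principal component scores, were compared with exact permutation tests, which cannot give a p under 0.0286 for 4 arrays against 4.

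Before the data were examined, 45 gene lists were fixed, along with the samples, the design and most alternatives. Of their 709 entries, 626 matched a named gene. The list of mitochondrially encoded genes had no matched member and was not analysed here, and 44 lists were tested. Each list was tested with limma's camera, with a preset correlation between genes of 0.01 and adjustment over the 44 lists. Camera was repeated with a correlation estimated for each list, and fry was run as a self-contained test. The lists cover metabolism, stress, cell cycle, T cell states and signalling, markers of other spleen cells, and ribosomal protein and histone genes as a view of RNA quality.

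Genes are named by a rule of the same date. It takes the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap. Their mean level had to be at or above the percentile 40 of all genes (a log2 value of 4.74), and predicted, unnamed, microRNA, small nucleolar, receptor segment and olfactory genes were left out. It also takes up to 4 members of each list with the smallest p, and 15 T cell genes in every case. Of these 15, 13 were matched, and 2, Foxp3 and Lck, were not matched and were not analysed here. Hif1a, Cd8b1 and Nr4a1 fall outside the parts of the rule under which they are printed and were chosen after their values were seen.

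The fit was tested on simulated data for the comparison of hBD-2 with PBS, with 19505 genes at their measured means and spreads and 200 seeded changes. It recovered 12% of genes seeded at 1.25-fold, 54% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, of 50 each. False calls numbered 10, which was 6.58% of all calls, and the seeded glycolysis list was the 1 list past the threshold. Noise was drawn independently for each gene, so the simulation cannot show how camera's preset correlation fares when genes move together. The 200 seeded genes lay at or above the percentile 40 of mean level and outside all lists, so recovery of dimmer genes was not tested.

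Alternatives were the replicate number as a fixed or random block, leaving out dim genes, a variance trend with robust estimation, array weights, other normalizations (quantile, median centring, cyclic loess), the mean of a gene's probe sets, all probe sets, a test against a fold of 1.1, and leaving out each array or both arrays of a number. Removing each array's level trend, and leaving out hBD-2 replicates 3 and 4 together, were chosen after the data were seen.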

Results

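The data comprised 8 arrays of mouse splenic T cells, a mixture of CD4 and CD8 cells stimulated through CD3 and CD28 for 48 h, with 4 arrays from cells kept with the vehicle PBS and 4 from cells kept with hBD-2. Human beta-defensin-2 is a small cationic antimicrobial peptide of epithelial surfaces. The comparison asks which genes differ in activated T cells when the peptide is present. Values are deposited log2 RMA values and are given as mean ± SD with n = 4 arrays a group.

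Expression profiles were close to each other, with Pearson correlations across genes of 0.990 to 0.994 within groups and 0.983 to 0.993 between groups. The first principal component held 38.8% of the variance and parted the groups, at -16.03 ± 7.09 (SD, n = 4) for PBS and 16.03 ± 11.2 for hBD-2 (exact permutation test, two-sided, p = 0.0286, the smallest that 4 arrays against 4 can give). The spread of values on an array also differed in mean. The interquartile range was 3.68 ± 0.0549 log2 units on the PBS arrays and 3.53 ± 0.0936 on the hBD-2 arrays (exact permutation test, two-sided, p = 0.0571, n = 4), and hBD-2 replicates 3 and 4 had the narrowest ranges, 3.45 and 3.46. This difference ran alongside every gene group described here.

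**Figure D1:**
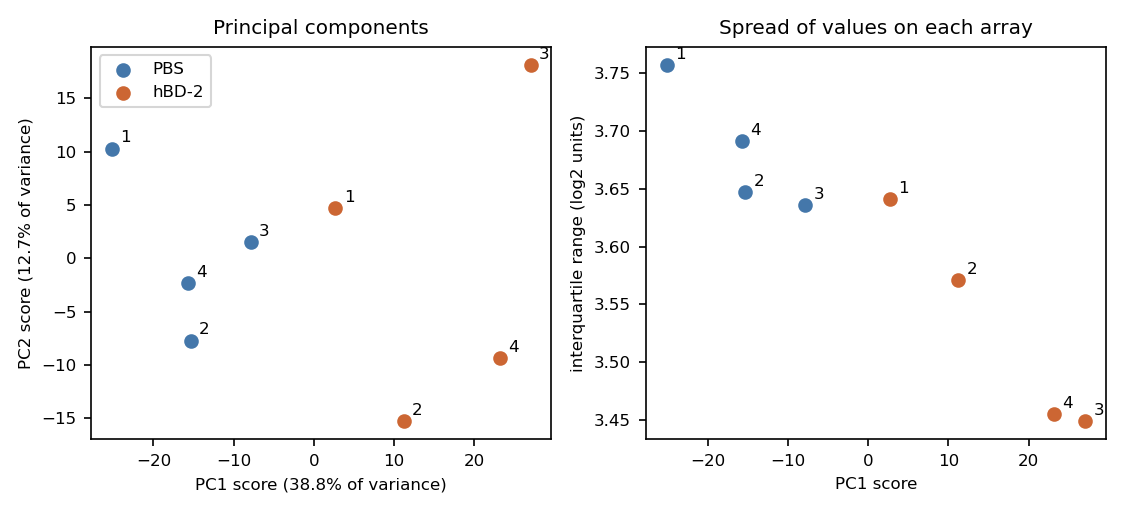
The left panel plots the 8 arrays by their scores on the first and second principal components (38.8% and 12.7% of the variance), and the right panel plots each array's interquartile range of log2 values against its first score. Points are single arrays, numbers are replicate numbers and colours are groups; PBS arrays lie below 0 on the first component and hBD-2 arrays above 0, and hBD-2 replicates 3 and 4 have the highest scores and the narrowest ranges.

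In cells kept with hBD-2, 17 of 18 cholesterol synthesis genes, 8 of 10 fatty acid synthesis genes, 16 of 18 glycolysis genes and 11 of 24 Th1 and cytotoxic effector genes fell, the other members not passing the threshold. Tested as lists against other genes, 0 of 44 passed with an estimated correlation (adjusted p = 0.0838, 0.136, 0.136 and 0.0838 for these 4). Of 19505 genes, 869 changed, 156 upward and 713 downward, so that 82.0% of the changed genes were lower. Over all 19505 genes, changed or not, 46.1% had a log2 fold change below 0, and the median was 0.02. A change of at least 1.5-fold was found for 345 genes (34 higher and 311 lower), and one of at least 2-fold for 73 (3 higher and 70 lower). In 855 of the 869 genes the groups did not overlap. Over all genes, 14.9% did not overlap, against 2.86% by chance. With quantile normalization repeated, 234 genes were higher and 506 lower, a share of 68.4% lower. The share was 71.7% with cyclic loess (224 higher, 568 lower) and 71.6% with each array's level trend removed (227 higher, 573 lower). The count of changed genes was 312 without PBS replicate 1, 338 without PBS replicate 2, 373 without PBS replicate 4, 390 without hBD-2 replicate 3, 363 without hBD-2 replicate 4 and 1396 without hBD-2 replicate 1. In the same order, the higher genes numbered 33, 39, 48, 51, 50 and 322 and the lower genes 279, 299, 325, 339, 313 and 1074, and 89 were higher without hBD-2 replicate 2. Changes of at least 1.5-fold numbered 553 (74 higher and 479 lower) without hBD-2 replicate 1, and 21 such genes were higher without PBS replicate 1.

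The largest fall among the named genes was that of Fads2, a fatty acid desaturase, from 9.08 ± 0.168 to 6.87 ± 0.275, or 4.64-fold (log2 fold change -2.22, SE 0.140, limma adjusted p = 3.06e-05). Aldoc, a glycolytic aldolase, fell 4.49-fold, from 9.36 ± 0.128 to 7.19 ± 0.177 (log2 fold change -2.17, SE 0.112, limma adjusted p = 6.04e-06). The metallothioneins Mt2 and Mt1, which bind zinc and copper, fell 3.87-fold and 2.95-fold. Ccr2, a chemokine receptor, fell 3.64-fold, and Slamf7, a surface receptor of the SLAM family, fell 3.35-fold. The desaturase Scd1, the glucose transporter Slc2a3, the hypoxia-responsive gene Ndrg1, the isoprenoid enzyme Idi1, the mitochondrial protein gene Mgarp and the oxygen sensor Egln3 had log2 fold changes between -1.77 (Scd1) and -1.57 (Egln3). The naming rule required that the groups not overlap, so the lack of overlap in all of these is no separate result.

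Rises were smaller. Phlda3, a p53 target, rose 2.21-fold, from 4.37 ± 0.0533 to 5.52 ± 0.126 (log2 fold change 1.15, SE 0.0934, limma adjusted p = 0.000165). Mmp12, a metalloproteinase, rose 2.21-fold with an SE of 0.210 on the log2 scale (limma adjusted p = 0.0117). Cd80, a ligand of CD28 and CTLA-4, rose 2.10-fold, from 6.67 ± 0.200 to 7.74 ± 0.330 (limma adjusted p = 0.00430). The carboxypeptidase Cpa3 rose 1.98-fold and the urokinase receptor gene Plaur 1.97-fold. Celf5, Dglucy, Zmat3, Safb, Prrg4, Myb and Pnliprp1 rose between 1.57-fold (Pnliprp1) and 1.79-fold (Celf5). The call of Celf5 was lost when any of 5 single arrays was left out (highest limma adjusted p = 0.0809).

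**Figure D2:**
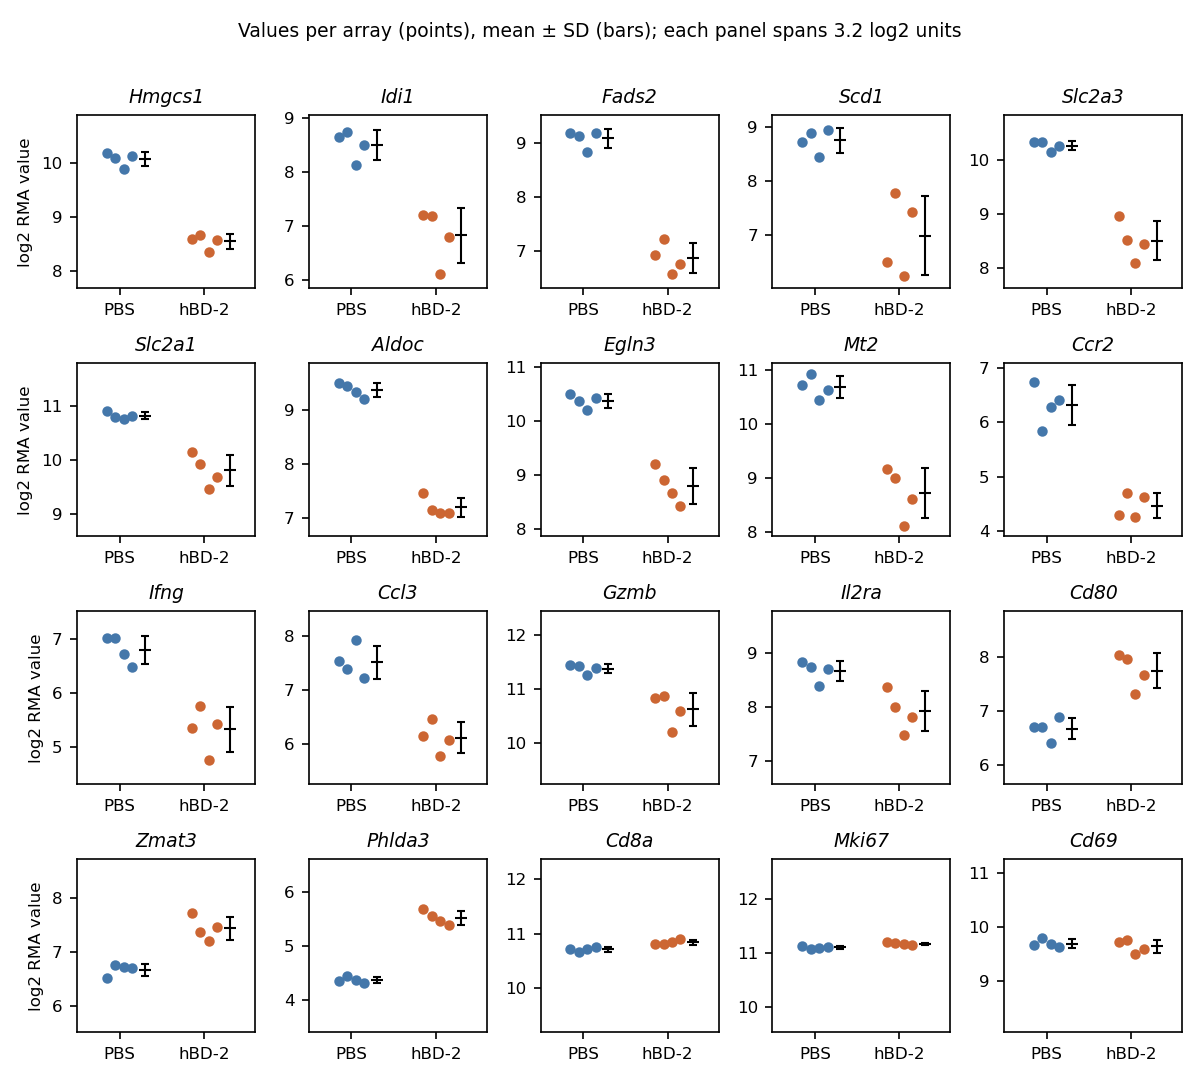
Each panel plots the log2 RMA value of 1 gene on the 4 PBS and the 4 hBD-2 arrays (points), with the mean and SD of each group (bars), on vertical axes that span the same number of log2 units. Hmgcs1 fell from 10.1 to 8.55 and Cd80 rose from 6.67 to 7.74 without overlap. The means of Mki67 (11.1 and 11.2) and Cd69 (9.70 and 9.64) lay close together, although all 4 hBD-2 values of Mki67 lay slightly above its 4 PBS values.

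Cholesterol synthesis genes fell nearly throughout. Of 18 measured members of the cholesterol synthesis and uptake list, 17 fell, none rose and 1 was not past the threshold, and 18 fell when adjusted over the list alone. The median log2 fold change was -1.21 (camera adjusted p = 1.51e-28; adjusted p = 0.0838 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, fell 2.88-fold, from 10.1 ± 0.130 to 8.55 ± 0.134. The later pathway enzymes Msmo1, Nsdhl and Lss fell 2.90-fold, 2.76-fold and 2.26-fold. Fatty acid synthesis genes fell in 8 of 10 members (9 adjusted over the list alone), with a median of -0.80 (camera adjusted p = 2.97e-11; adjusted p = 0.136 with an estimated correlation). Besides Fads2 and Scd1, the list's falling members included Acly, which makes cytosolic acetyl-CoA, and Fasn, the fatty acid synthase, both 1.81-fold lower.

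Glycolysis genes fell in 16 of 18 members, with a median log2 fold change of -0.73 (camera adjusted p = 1.51e-18; adjusted p = 0.136 with an estimated correlation). Adjusted over the list alone, 17 fell and 1 rose, the latter being Hif1a, a transcription factor of the hypoxia response, at 10.5 ± 0.102 and 10.8 ± 0.0370 (limma adjusted p = 0.110 over all genes). The lactate exporter gene Slc16a3 fell 2.27-fold, the glucose transporter gene Slc2a1 2.02-fold, Pgam1 1.93-fold and Pfkl 1.83-fold. Of 16 other hypoxia-inducible genes, 11 fell (14 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 1.57e-15; adjusted p = 0.0838 with an estimated correlation). Ero1a, an oxidase of the endoplasmic reticulum, fell 2.42-fold, and Ankrd37 fell 1.90-fold. Of nuclear-encoded oxidative phosphorylation genes, 2 of 18 members fell (10 adjusted over the list alone) with a median of -0.26 (camera adjusted p = 1.02e-07; adjusted p = 0.235 with an estimated correlation), or -0.17 with quantile normalization. The falling members were Ndufa4, 1.41-fold lower, and Atp5o, 1.38-fold lower. Atp5o lost its call with quantile normalization repeated, and both lost it without any of 5 or 6 single arrays (highest limma adjusted p = 0.0766 and 0.0946).

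**Figure D3:**
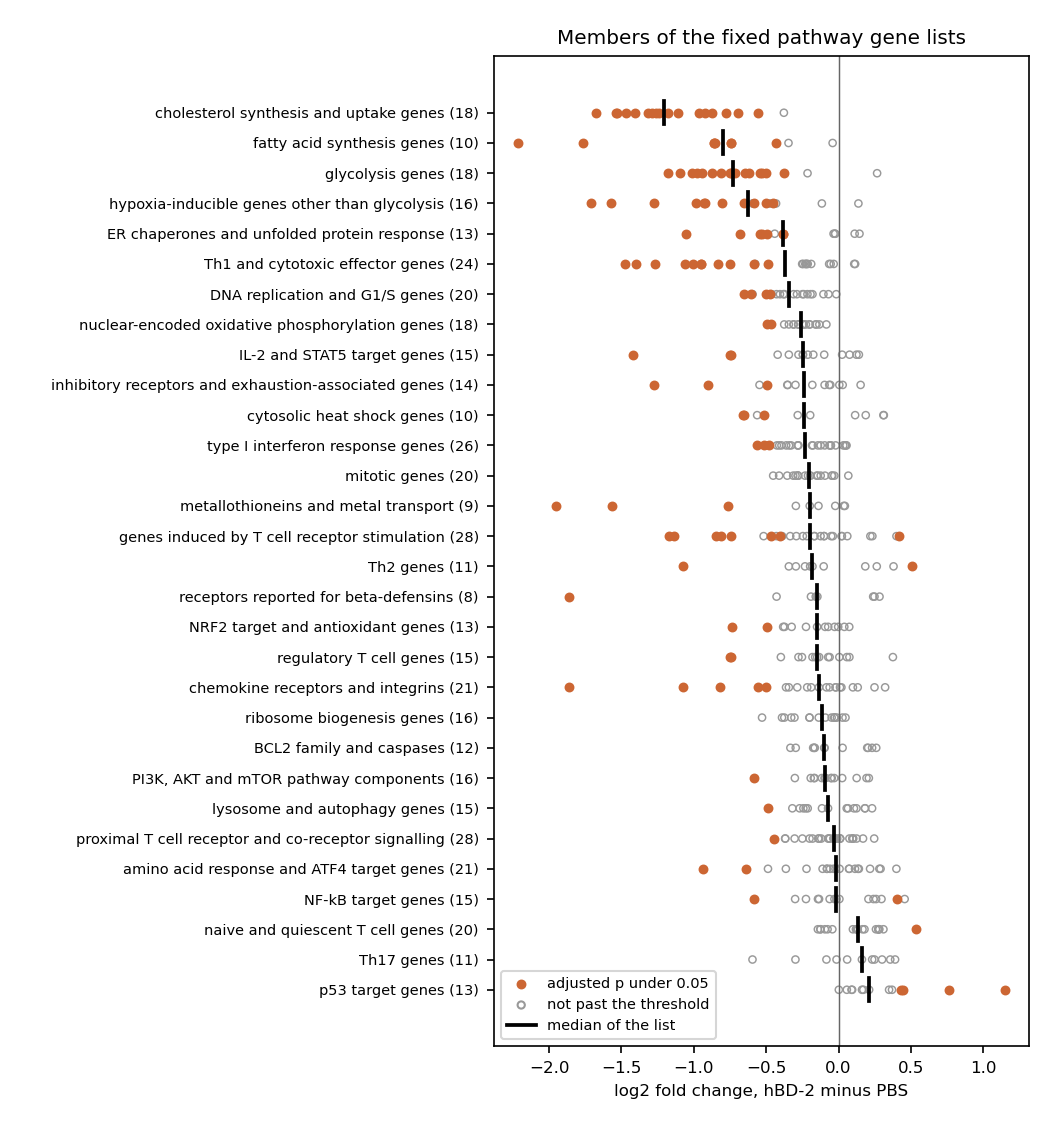
Each line holds the log2 fold changes (hBD-2 minus PBS, horizontal axis) of the measured members of 1 gene list, with their number in brackets; filled points are genes with a limma adjusted p under 0.05, open points are other genes and black ticks are list medians. Among these pathway lists (marker lists are not drawn), the cholesterol list has the lowest median, -1.21, and the p53 target list the highest, 0.21.

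Effector genes of Th1 and cytotoxic T cells fell in 11 of 24 members, none rose, and 12 fell when adjusted over the list alone. The median was -0.37 (camera adjusted p = 2.23e-11; adjusted p = 0.0838 with an estimated correlation). Ifng, the gene of interferon gamma, fell 2.78-fold, from 6.80 ± 0.260 to 5.33 ± 0.418 (limma adjusted p = 0.00204). The chemokine genes Ccl3 and Ccl5 fell 2.63-fold and 1.93-fold, Gzmk 2.41-fold and Prf1 (perforin) 1.93-fold. Tnf fell, with a log2 fold change of -0.59 (limma adjusted p = 0.0441), but its call was lost with quantile normalization repeated, with cyclic loess, with the level trend removed and without any of 6 single arrays (highest limma adjusted p among these omissions = 0.117).

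The Th2 list (11 members) was not past the threshold (camera adjusted p = 0.553). Its members Ccr4 fell 2.11-fold and Il9 rose 1.42-fold, with 2 rising and 1 falling when adjusted over the list alone, while Il4 had a log2 fold change of -0.29 (limma adjusted p = 0.153) and Il13 one of 0.38 (limma adjusted p = 0.0729). Il9 (3.22 ± 0.109 and 3.73 ± 0.223) and Il4 (3.45 ± 0.170 and 3.16 ± 0.139) lay near or below the arrays' lower quartiles, 3.62 to 3.78. Both genes are thus close to the floor. Ccr4 was at 4.97 ± 0.338 and 3.89 ± 0.436. Il9 lost its call under quantile normalization and without any of 6 single arrays (highest limma adjusted p = 0.109), and Ccr4 without either of 2 (0.0516). In the Th17 list none of 11 members passed, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.381). Il17a was at 5.22 ± 0.126 and 5.61 ± 0.155 (limma adjusted p = 0.0635), Stat3 had a log2 fold change of -0.30 and Rora one of -0.59. Of 15 regulatory T cell genes, 2 fell, Il2ra and Ebi3, a cytokine subunit (1 rose and 3 fell adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0421; adjusted p = 0.277 with an estimated correlation). Foxp3 is an entry of the regulatory T cell list but was not matched, so the list was tested without it. Ikzf2 had a log2 fold change of 0.38 (limma adjusted p = 0.0721). The call of the list was lost with quantile normalization (0.129), and without PBS replicate 1 (0.0518), PBS replicate 3 (0.0604), hBD-2 replicate 2 (0.120) or hBD-2 replicate 4 (0.0623).

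Genes induced by T cell receptor stimulation were mixed, with 7 of 28 falling and 1 rising (12 and 2 adjusted over the list alone) and a median of -0.19 (camera adjusted p = 8.92e-05; adjusted p = 0.392 with an estimated correlation). The median was -0.10 with quantile normalization and -0.12 with cyclic loess or the level trend removed. Tnfrsf9, the co-stimulatory receptor 4-1BB, fell 2.25-fold, the transcription factor gene Nfil3 2.20-fold, and the transferrin receptor gene Tfrc 1.75-fold, and Zbtb32 had a log2 fold change of -0.85. Il2ra, the alpha chain of the interleukin-2 receptor, fell 1.67-fold (limma adjusted p = 0.0342), a call lost without any of 6 single arrays (highest limma adjusted p = 0.0977). The rising member was Nr4a1, 1.34-fold higher, a call lost without any of 7 single arrays (highest limma adjusted p = 0.110). Cd69 (9.70 ± 0.0758 and 9.64 ± 0.123) and Il2 (3.73 ± 0.314 and 3.96 ± 0.159) were not past the threshold (limma adjusted p = 0.795 and 0.384). Il2 lay near the arrays' lower quartiles, 3.62 to 3.78, and thus close to the floor, where a change may not show.

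Proximal T cell receptor signalling genes were not past the threshold as a list (28 members, camera adjusted p = 0.164). Its median of -0.03 was -0.06 without PBS replicate 2 or hBD-2 replicate 1, and turned to 0.04, 0.05 and 0.04 with quantile normalization, cyclic loess and the level trend removed. Themis was its 1 falling member, over all genes and over the list alone, 1.37-fold lower, a call lost with quantile normalization and without any of 7 single arrays (highest limma adjusted p = 0.0814). Zap70, Csk, Ptpn6 and Malt1 had log2 fold changes of -0.25, -0.30, -0.37 and -0.37 (limma adjusted p from 0.0889 to 0.189). Of 20 naive and quiescent T cell genes, Klf3 rose 1.45-fold (1 adjusted over the list alone), a call lost without any of 7 single arrays (highest limma adjusted p = 0.128), and the median was 0.13 (camera adjusted p = 0.0139; adjusted p = 0.493 with an estimated correlation, and 0.0508 by camera without PBS replicate 2). That median was 0.20 without PBS replicate 3, and 0.23, 0.22 and 0.21 with quantile normalization, cyclic loess and the level trend removed. Foxp1, Lef1 and Btg1 had log2 fold changes of 0.27, 0.28 and 0.31 without passing. Interleukin-2 and STAT5 target genes fell in 3 of 15 members (4 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00114; adjusted p = 0.392 with an estimated correlation), or -0.15 with quantile normalization and -0.16 with the level trend removed. Without hBD-2 replicates 3 and 4 together the call of that list was lost (median -0.07, camera adjusted p = 0.0818). Among them Prdm1, a regulator of effector differentiation, fell 2.68-fold and the granzyme gene Gzmb 1.68-fold.

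Inhibitory receptor genes fell in 3 of 14 members (6 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.000106; adjusted p = 0.0838 with an estimated correlation). Havcr2 fell 2.42-fold, Cd160 1.87-fold and Lag3 1.41-fold, while Tigit had a log2 fold change of -0.55 (limma adjusted p = 0.0530). The call of Lag3 was lost without any of 5 single arrays (highest limma adjusted p = 0.0890). Chemokine receptor and integrin genes fell in 5 of 21 members (7 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.000767; adjusted p = 0.146 with an estimated correlation), or -0.21 without hBD-2 replicate 4 and -0.08 with quantile normalization. These included Ccr2, Ccr4 and the integrin chains Itgb1 and Itgb2, the last 2 being 1.47-fold and 1.41-fold lower. Among 8 receptors reported for beta-defensins, 1 fell, Ccr2 (2 rose and 2 fell adjusted over the list alone), and the list was not past the threshold (median -0.15, camera adjusted p = 0.247). Ccr6 was at 4.74 ± 0.460 and 4.99 ± 0.598 (limma adjusted p = 0.652).

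Genes of DNA replication and the G1/S transition fell in 4 of 20 members (13 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 1.23e-08; adjusted p = 0.321 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell 1.58-fold and Tyms, thymidylate synthase, 1.52-fold. Uhrf1 fell 1.42-fold and Mcm5 1.39-fold. Tyms, Uhrf1 and Mcm5 each lost the call without any of 6 single arrays (highest limma adjusted p = 0.0764, 0.0893 and 0.116), and Mcm5 also with quantile normalization. None of 20 mitotic genes passed over all genes (8 fell adjusted over the list alone), and the median was -0.20 (camera adjusted p = 2.73e-05; adjusted p = 0.392 with an estimated correlation), or -0.13, -0.12 and -0.13 with quantile normalization, cyclic loess and the level trend removed. Aurkb, Cdk1, Bub1 and Birc5 had log2 fold changes of -0.35, -0.45, -0.41 and -0.30, and the proliferation marker Mki67 was at 11.1 ± 0.0301 and 11.2 ± 0.0204 (limma adjusted p = 0.671). Ribosome biogenesis genes had no member past the threshold, of 16, over all genes or over the list alone (median -0.11, camera adjusted p = 0.0235; adjusted p = 0.493 with an estimated correlation). That list lost its call with quantile normalization (0.278) and without PBS replicate 1 (0.0637), PBS replicate 4 (0.0592) or hBD-2 replicate 3 (0.0764). Its median was -0.19 without PBS replicate 3, -0.17 without hBD-2 replicate 1, and -0.03, -0.04 and -0.04 with quantile normalization, cyclic loess and the level trend removed.

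Targets of the tumour suppressor p53 rose in 4 of 13 members and none fell (6 rose adjusted over the list alone), with a median of 0.21 (camera adjusted p = 2.21e-05; adjusted p = 0.146 with an estimated correlation). Besides Phlda3, Zmat3 rose by 0.77 on the log2 scale, Ei24 1.36-fold and Ccng1 1.35-fold. The calls of Ei24 and Ccng1 were lost without any of 6 single arrays (highest limma adjusted p = 0.0912 and 0.0831). Metallothionein and metal transport genes fell in 3 of 9 members (3 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.00099; adjusted p = 0.136 with an estimated correlation) or -0.38 without PBS replicate 4, these being Mt1, Mt2 and the zinc importer gene Slc39a10 (log2 fold change -0.76).

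Markers of cell types and of RNA quality were compared in the same way. Cd4 was at 9.77 ± 0.0989 and 9.81 ± 0.147 (limma adjusted p = 0.888) and Cd8a at 10.7 ± 0.0410 and 10.8 ± 0.0417 (limma adjusted p = 0.390). The CD4 list had no member past the threshold, of 5, over all genes or over the list alone (camera adjusted p = 0.443), and the CD8 list had 1 of 6 falling, Ly6c2, 1.42-fold lower (3 adjusted over the list alone; camera adjusted p = 0.237). Natural killer cell markers had 1 of 8 falling, the granzyme gene Gzma, 2.08-fold lower (2 adjusted over the list alone), and a median of -0.19 (camera adjusted p = 0.0195; adjusted p = 0.146 with an estimated correlation, and 0.0604 by camera without PBS replicate 3). Erythroid markers had 1 of 6 rising, Klf1, 1.34-fold higher (2 adjusted over the list alone), and a median of 0.23 (camera adjusted p = 0.0235; adjusted p = 0.211 with an estimated correlation, 0.0657 by camera with quantile normalization and 0.0541 without PBS replicate 4). Klf1 lost its call with quantile normalization and without any of 7 single arrays (highest limma adjusted p = 0.119), and Car1 had a log2 fold change of 1.20 with an SE of 0.376 (limma adjusted p = 0.0921). With the replicate number as a fixed block, the limma adjusted p was 0.00069 for Car1 and 0.0684 for Klf1.

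The lists of B cell, neutrophil, dendritic cell, platelet, stromal and gamma-delta or natural killer T cell markers had no member past the threshold over all genes, and their camera adjusted p-values were 0.103, 0.237, 0.579, 0.237, 0.0709 and 0.826. Adjusted over the list alone, 1 platelet gene rose. The B cell list had all 10 members above 0 in log2 fold change, with a median of 0.24 and list means of 4.94 ± 0.392 (PBS) and 5.28 ± 0.679 (hBD-2), and its call changed with single arrays. The list mean was 5.21 and 5.35 on PBS replicates 2 and 4 and 5.89 and 5.83 on hBD-2 replicates 2 and 4, against 4.60 and 4.61 on PBS replicates 1 and 3 and 4.69 and 4.68 on hBD-2 replicates 1 and 3. The list passed camera without PBS replicate 4 (median 0.45, adjusted p = 0.0259), hBD-2 replicate 1 (0.43, adjusted p = 0.0176) or hBD-2 replicate 3 (0.44, adjusted p = 0.00696), and its median was 0.10 without hBD-2 replicate 2 (adjusted p = 0.492) and 0.15 without hBD-2 replicate 4 (adjusted p = 0.403). With an estimated correlation over all 8 arrays its adjusted p was 0.598. With the replicate number as a fixed block the B cell list passed camera (adjusted p = 0.00497), but no list passed with that block and an estimated correlation. The stromal list (median 0.17) passed camera without hBD-2 replicate 2 (adjusted p = 0.0387) or hBD-2 replicate 3 (adjusted p = 0.0452), and its adjusted p was 0.290 with an estimated correlation. Of 14 macrophage and monocyte markers, Ccr2, Hmox1 and Itgam fell (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.424), and the calls of Itgam and Hmox1 were lost without any of 7 and 3 single arrays (highest limma adjusted p = 0.126 and 0.0540). Of 6 plasma cell markers, Prdm1 fell (2 adjusted over the list alone; camera adjusted p = 0.538). Ribosomal protein genes, abundant in all cells, had none of 12 members past the threshold over all genes or over the list alone (median 0.0083, camera adjusted p = 0.799). Histone genes fell in 2 of 16 members, H1f5 and H1f1 (3 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00136; adjusted p = 0.392 with an estimated correlation), and both genes lost their calls with quantile normalization and without any of 7 single arrays (highest limma adjusted p = 0.110 and 0.124). Among these marker and RNA quality lists, the median and the mean differed in sign for the CD4 (0.02 and -0.10), plasma cell (0.09 and -0.23), macrophage (0.04 and -0.16), gamma-delta (-0.0066 and 0.05) and ribosomal protein (0.0083 and -0.01) lists, with the camera direction following the mean. The medians of these 5 lists each changed sign without at least 1 of the 8 arrays, that of the macrophage list also with quantile normalization, cyclic loess and the level trend removed, and those of the CD4 and ribosomal protein lists with median centring.

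In all, 23 of the 44 lists passed camera with the preset correlation, 20 lower and 3 higher, and 0 passed with an estimated correlation, where 12 lists had an unadjusted camera p under the threshold. Without hBD-2 replicates 3 and 4, the arrays with the narrowest ranges, an omission chosen after seeing the data, 128 genes changed (16 higher and 112 lower). Then 18 lists passed camera, and the lists of regulatory T cells, naive cells, ribosome biogenesis, interleukin-2 and STAT5 targets and erythroid markers did not (camera adjusted p = 0.0761, 0.0731, 0.318, 0.0818 and 0.0706). Among the lists that passed, the median was -0.11 for activation-induced, -0.18 for G1/S, -0.10 for mitotic, -0.17 for oxidative phosphorylation, -0.12 for metallothionein and 0.38 for p53 target genes. Fry, which does not compare a list with other genes, called 26 lists in 1 direction. Over all genes, 4341 had an unadjusted limma p under the threshold. Of the 92 changed genes among the 119 looked at by name, 60 kept the call without each single array, and 51 lost it without hBD-2 replicates 3 and 4 together.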

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

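No cause was tested for the values in this part, and the rule that set them apart was chosen before the data were seen. In each group of 4 arrays, the lowest or highest array was set apart when its gap to the nearest other exceeded 0.829 of the group's range. Chance does this for about 1 in 20 groups, or 16.4 of the 328 looked at, and 30 were found; genes that move together are not independent. PBS replicate 3 held 11 of them, 10 on the side of the hBD-2 group, and hBD-2 replicate 1 held 6, all 6 on the side of the PBS group.

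On PBS replicate 3, log2 values stood below the other PBS arrays for Fads2 (8.84, others 9.13 to 9.19), Lss (8.42, others 8.69 to 8.71), Pgam1 (9.68, others 9.88 to 9.91), Mcm3 (9.27, others 9.44 to 9.47) and Vldlr (6.23, others 6.39 to 6.40). The same held for Hspd1 (9.66, others 9.86 to 9.89), Pik3cg (8.20, others 8.39 to 8.42), Prdm1 (5.34, others 5.77 to 5.81) and the mean of the unfolded protein response list (8.78, others 8.90 to 8.91). Dglucy (5.83, others 5.67 to 5.70) and the mean of the T cell receptor signalling list (9.67, others 9.63) stood above them on that array.

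On hBD-2 replicate 1, values stood above the other hBD-2 arrays for Aldoc (7.46, others 7.09 to 7.14), Xbp1 (8.96, others 8.37 to 8.44), Hsph1 (8.05, others 7.68 to 7.70) and Pik3cg (7.97, others 7.70 to 7.72). The means of the T cell receptor signalling list (9.64, others 9.54 to 9.56) and the interferon list (6.76, others 6.63 to 6.65) did so too.

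On hBD-2 replicate 4, Mgarp (5.13, others 4.19 to 4.33) and Il9 (4.06, others 3.60 to 3.64) were high, and Ccr4 (3.25, others 4.03 to 4.19) and Birc5 (8.67, others 8.77 to 8.78) were low. On hBD-2 replicate 3, Nfkbia (8.91, others 8.74 to 8.75) was high, and Irf7 (7.13, others 7.29 to 7.31) and Acly (8.20, others 8.45 to 8.50) were low. Gzmk (5.56, others 5.11 to 5.17) and the mean of the heat shock list (7.73, others 7.58 to 7.60) were high on PBS replicate 1, where the mean of the stromal list (4.54, others 4.67 to 4.69) was low. On PBS replicate 2, Safb (7.64, others 7.79 to 7.82) and the mean of the PI3K and mTOR list (8.79, others 8.80) were low, and on PBS replicate 4 Hif1a (10.7, others 10.5) was high.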

How the results depend on the processing

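Removing each array's level trend and leaving out hBD-2 replicates 3 and 4 together were chosen only after the data were seen. No called gene or list among those named turned its direction under any alternative. Up to 5 lists, counted by camera direction, and 1 gene that were not past the threshold changed sign under a scaling. By their medians instead, the lists that changed sign under a scaling were those of T cell receptor signalling, amino acid response, NF-kB targets (-0.01, or 0.08 with quantile normalization), PI3K and mTOR, CD4, macrophage and ribosomal protein genes. Array weights, the mean of probe sets and median centring left all 23 list calls in place and ended at most 2 of 92 gene calls, while quantile normalization ended 9 gene and 3 list calls (the lists of regulatory T cells, ribosome biogenesis and erythroid markers), and cyclic loess and trend removal 7 and 3 each. Where the cause is not given, the cause was not tested. Dim genes lie near the array's floor, where signal over background limits what can be seen.

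The 869 changed genes (156 higher, 713 lower) became 1408 (313 and 1095) without the dimmest genes, where fewer genes were tested, 2033 (479 and 1554) with a variance trend and robust estimation, and 283 (22 and 261) against a fold of 1.1, a stricter question. Without hBD-2 replicates 3 and 4, with fewer arrays, they became 128 (16 and 112), of which 126 (15 and 111) were at least 1.5-fold; 51 of 92 gene calls and 5 of 23 list calls ended, and called medians that moved by over 1.5 times went to -0.11 (activation), -0.18 (G1/S), -0.10 (mitotic), -0.17 (oxidative phosphorylation), -0.12 (metallothionein), 0.38 (p53), -0.07 (interleukin-2 and STAT5) and 0.15 (erythroid). Camera with an estimated correlation called 0 lists in place of 23, with or without the replicate block, and fry's mixed test, which asks another question, called 36. The share of the first component, 38.8%, became 47.4% without the dimmest genes, 36.1% with quantile normalization, 36.05% with cyclic loess and 36.04% with trend removal.

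Leaving out 1 array gave 312 (without PBS replicate 1) to 1396 (without hBD-2 replicate 1) changed genes, 33 to 322 higher and 279 to 1074 lower; 232 to 553 at least 1.5-fold, 21 to 74 higher and 211 to 479 lower; 21 to 25 lists; and a first component of 37.9% to 43.5%. The count was 338 without PBS replicate 2, 373 without PBS replicate 4, 390 without hBD-2 replicate 3 and 363 without hBD-2 replicate 4. Leaving out both arrays of a number gave 128 (number 4) to 604, 10 to 88 higher and 118 to 516 lower; 128 to 414 at least 1.5-fold, 10 to 44 higher and 118 to 370 lower; and 20 to 24 lists.

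The labels do not say whether the replicate numbers pair the arrays. Deviations of same-numbered arrays correlated across genes at 0.18, 0.059, 0.16 and 0.0048, and 5 of 8 arrays correlated best with their own number. The mean of the B cell list was higher on numbers 2 and 4 than on numbers 1 and 3 in both groups. Car1 was highest on number 3 in both groups. These are hints of pairing from the data and not the design. With the number as a fixed block 857 genes were called, 704 of them also without it and all 704 in the same direction; as a random block 287 genes were higher. The fixed block added 1 list call, B cell markers (camera adjusted p = 0.00497, against 0.103 without it and 0.394 with the block and an estimated correlation), and ended none. Among the named genes it added Car1 (limma adjusted p = 0.00069, against 0.0921 without it) and Cdk1 (0.0414) and ended the calls of Oas2 (0.0543), Klf1 (0.0684) and H1f5 (0.055). The random block added Il17a (0.0421), Tigit (0.037), Aurkb (0.0382), Cdk1 (0.0409) and Bub1 (0.0467). With the block, leaving out both arrays of a number gave 110 (number 4) to 375 genes, 5 to 50 higher and 105 to 325 lower, with 335 (24 and 311) without number 1 and 185 (19 and 166) without number 3, all 185 at least 1.5-fold; 110 to 360 at least 1.5-fold, 5 to 46 higher (22 without number 1) and 105 to 314 lower; and 22 to 24 lists.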

Other observations

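The tests against the T cell receptor list, the mitotic list, Cd8a and Cd8b1, and the natural killer genes, and the removal of each array's level trend, were chosen only after the result was seen. Genes of protein folding in the endoplasmic reticulum fell in 7 of 13 members of the unfolded protein response list (8 adjusted over the list alone), with a median log2 fold change of -0.38 (camera adjusted p = 0.0001; adjusted p = 0.146 with an estimated correlation). The disulfide isomerase Pdia6 fell 2.07-fold, Xbp1 1.61-fold, Calr 1.41-fold and Hsp90b1 1.30-fold. Heat shock genes had 3 of 10 falling, Hspd1, Hsph1 and Hsp90aa1 (1 rose and 5 fell adjusted over the list alone). The camera adjusted p of that list was 0.0722, 0.0355 without hBD-2 replicate 1 and 0.450 with an estimated correlation. Type I interferon response genes fell in 3 of 26 members (10 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.21e-05; adjusted p = 0.146 with an estimated correlation), these being Dhx58, 1.48-fold, Irf7, 1.43-fold, and Oas2, 1.40-fold lower. Xbp1, Calr, Hsp90b1, the 3 heat shock genes and Oas2 lost their calls when any of 5 to 7 single arrays was left out (highest limma adjusted p = 0.115, for Oas2).

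Antioxidant genes fell in 2 of 13 members, Hmox1 and Prdx1 (6 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00213; adjusted p = 0.188 with an estimated correlation). The median was -0.10 without PBS replicate 4, -0.22 without hBD-2 replicate 3, and -0.07, -0.07 and -0.08 with quantile normalization, cyclic loess and the level trend removed. Of 21 amino acid response genes, Vldlr fell 1.91-fold and Eif4ebp1 1.56-fold (2 adjusted over the list alone; camera adjusted p = 0.680). Of 16 PI3K and mTOR genes, Pik3cg fell, with a log2 fold change of -0.58 (1 adjusted over the list alone; camera adjusted p = 0.142), and of 15 lysosome and autophagy genes, Ctsb fell 1.40-fold (1 adjusted over the list alone; camera adjusted p = 0.381). In the NF-kB target list Nfkbia rose 1.32-fold and Tnf fell (1 and 1 adjusted over the list alone). That list had a median of -0.01 but a mean of 0.025, and the camera direction followed the mean (camera adjusted p = 0.778). No BCL2 family or caspase gene passed, of 12, over all genes or over the list alone (camera adjusted p = 0.784). The calls of Prdx1, Eif4ebp1, Ctsb and Nfkbia were lost without any of 5 or 6 single arrays, and that of Hmox1 without any of 3 (highest limma adjusted p = 0.0863, for Prdx1).

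Splits of the 8 arrays bear on chance. Of 35 splits into 4 and 4, 1, the real one, gave as many as 869 changed genes, the highest other giving 6. Likewise 1 gave as many as 345 genes at least 1.5-fold, the highest other giving 6. Being 1 of 35 is the most that these splits can show. The other splits mix PBS and hBD-2 arrays, so a group difference widens their spread and lowers their counts. If same-numbered arrays share a mouse, fewer splits keep the pairs. The splits therefore do not exclude chance for these counts. For the lists, 1 of 35 gave as many as 23, but the highest other gave 22, so a count of lists past camera's preset correlation sets the groups apart by 1 list.

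More genes fell than rose among the 869 changed genes (82.0% lower), while 46.1% of all genes tested had a log2 fold change below 0, and the hBD-2 arrays had the narrower spread of values. If that spread were the whole cause, removing each array's level trend could be expected to bring the share of lower genes near an even split. The share was 71.6% with the trend removed (69.7% to 83.1% with 1 array left out), against 82.0% before, so the data argue against the spread as the whole cause, while the drop is consistent with a part in it. Whether the spread itself comes from RNA amount, hybridisation or the cells was not tested.

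The cholesterol, fatty acid, glycolysis and hypoxia lists were all lower by camera with the preset correlation, and none passed with an estimated one (adjusted p = 0.0838, 0.136, 0.136 and 0.0838). Against 10000 random lists of the same sizes matched on mean level, each of their medians lay at percentile 0. This argues against a narrower spread that acts by mean level alone as the whole cause. The random lists were drawn gene by gene, so an array effect on genes that move together stays open. The Th1 and cytotoxic, G1/S and interferon lists also lay at percentile 0. The shifts of the cholesterol, fatty acid, glycolysis and hypoxia lists exceeded that of the T cell receptor list by at least 0.613 (a difference of -0.613 for glycolysis). They exceeded that of the mitotic list by at least 0.478 (-0.478, glycolysis). Each difference had an exact permutation p of 0.0286, the smallest possible. The falls of the 4 lists had been seen before these comparisons were chosen, so this p adds no support. The receptor list had a median of -0.03, which argues against fewer T cells as the whole cause. The mitotic list had a median of -0.20, and fewer cycling cells need not shift all genes equally, so that explanation stays open. Timing of activation, viability and cell density were not measured here and stay open, as does an effect of hBD-2 itself.

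Of 24 Th1 and cytotoxic genes 11 fell and 13 did not pass, with a median of -0.37 over the list, which did not pass with an estimated correlation (adjusted p = 0.0838). Fewer CD8 cells could lower them. The lower bounds of the Cd8a and Cd8b1 log2 fold changes (estimate minus 2 SE) were -0.0368 and -0.0871. The median over the 11 called genes was -0.949 (-0.91 at most with 1 array left out). This argues against fewer CD8 cells as the whole cause for the called genes. In the CD8 list, however, 3 of 6 members fell when adjusted over the list alone (list median -0.10, camera adjusted p = 0.237). The mean of the CD8 list was lower on all 4 hBD-2 arrays than on every PBS array, so a smaller fall in CD8 cells stays open. The 11 genes were called in the same fit, so their median overstates the fall of the whole list, which was -0.37. Fewer natural killer cells stay open, because only 1 of 5 natural killer genes lay above a log2 level of 4.74, too few to test, although the isolation kit would remove such cells. Gzma is shared between the natural killer list and the Th1 and cytotoxic list.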
